A study of Neurospora crassa OR74A with 3 samples.

How the data were processed

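RNA sequencing libraries came from mycelia of 3 Neurospora crassa strains, 1 library per strain. Per the labels, mycelia were grown for 16 h in sucrose, washed and kept for 4 h in medium with 2% cellobiose, and total RNA was extracted with TRIzol and treated with DNase before Illumina library preparation. Groups were taken from the strain named in the labels, where clp1 is written as its locus, ncu05853. Nothing in the labels describes replicate cultures.

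The deposited tables give 3 values per gene. The read counts are whole numbers of reads per gene, made by the authors with TopHat as the aligner and HTSeq as the counter, per the submitters' processing notes. Their versions and settings, the genome build, the gene annotation and the use of strand are not given in the sources used here. The deposited RPKM values (reads per kilobase of exon, scaled to depth) were scaled by the authors on all reads in the file, assigned to genes or not. RPKM recomputed from the counts, the exon lengths and that total differed from the deposited values by at most 1.93e-08 of the value. The exon lengths are in bases, per the file headers, and served only for this check. RPKM was not used for any comparison, because counts were deposited.

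Each file holds 9730 genes and, apart from these, reads that name no gene. Reads outside genes made up 9.64% of all reads in Δ3βG, 8.41% in Δ3βGΔclp1 and 5.16% in Δ3βGΔcdt2Δclp1. Reads with several alignments made up 6.36%, 4.91% and 2.48%, and ambiguous reads 0.844%, 0.897% and 0.895%. These were left out of library sizes, leaving 8586155, 9465639 and 9808610 gene reads, or 83.2%, 85.8% and 91.5% of all reads. Reads that align to several places are not in the gene counts, so near-identical genes may be counted too low. With strand not stated, overlapping antisense genes cannot be separated.

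Gene symbols came from a RefSeq gene table of assembly NC12, which matched 9729 of the 9730 identifiers and gave 1118 of them a symbol. Since the authors' build is not named, the table served only for symbols and for which genes neighbour each other, and no coordinates are given. It holds no product names, so 4 lists defined by product name (cytosolic and mitochondrial ribosomal proteins, proteasome and cytochrome P450) were not used.

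Counts were scaled with the TMM factors of edgeR 4.0.16 (R 4.3.3), which were 1.10 for Δ3βG, 1.09 for Δ3βGΔclp1 and 0.833 for Δ3βGΔcdt2Δclp1. For each of 3 comparisons the log2 ratio of CPM, the reads scaled to library size, was computed with a prior of 0.5 counts scaled to library size. Ratios printed as a fold carry no prior and have an exact 95% interval (Clopper-Pearson, conditional on the sum of both counts). Intervals and floors cover counting error only, since reads made by PCR are not independent molecules. With 1 library per strain no test across replicates was possible, and genes were counted when at least 2-fold or 4-fold apart. The 6545 genes compared had a mean of at least 10 CPM on library totals over the 3 libraries, without the 5 deleted genes. A gene with 0 reads in one library was compared with a floor of 3 reads and its fold given as a lower bound, and no fold is given where both libraries had 3 reads or fewer.

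The design, the gene lists, the rule for named genes and most of the settings to be varied were fixed before the data were examined. The rule names the 12 genes with the highest and the 12 with the lowest log2 ratio in each comparison, and any list member with a mean of at least 10 CPM. Some list members under that mean are also named where a count of 5 or fewer falls on them; these were chosen after their values were seen. There were 15 lists: cellulases, lytic polysaccharide monooxygenases and cellobiose dehydrogenase, hemicellulases, pectin-degrading enzymes, remaining β-glucosidases, starch and sucrose hydrolases, sugar transporters, transcription factors of cellulase and carbon control, pentose catabolism, folding in the endoplasmic reticulum and secretion, glycolysis and fermentation, gluconeogenesis and glyoxylate cycle, conidia and aerial hyphae markers, clock and light, and heat shock and catalases. Members with a mean of at least 1 CPM were used. The median of each list was placed among medians of 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries. That mean was taken over all 3 libraries. In Δ3βGΔclp1 against Δ3βG, genes abundant only in Δ3βGΔcdt2Δclp1 were therefore matched to genes that can have far more reads in the libraries compared.

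For the overlap of the strains that lack clp1, unchanged libraries were simulated 100 times with Poisson counts from the Δ3βG profile. Scaling and ratios were tested on simulated counts of 9730 genes with the depths of the Δ3βGΔclp1 and Δ3βG libraries, 200 of the genes changed 4-fold. The changes were balanced, with 100 genes up and 100 down in 1 library. Changes as many and as large as those in Δ3βGΔcdt2Δclp1 were not simulated, so the scaling of that library was not tested. The simulated changes came out at medians of 2.02 and -1.99, and all were at least 2-fold apart. The interval held the simulated value for 90% of the higher, 96% of the lower and 95.0% of the unchanged genes.

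The settings varied were DESeq2 1.42.0 size factors, library totals, library totals without the 50 genes with most counts, a prior of 5 counts, no filter on low counts, a minimum of 50 CPM, and list members of at least 10 CPM. Scaling on all reads in the file and on library totals without eas were added after seeing the data. The other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.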

Results

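Messenger RNA levels were measured by RNA sequencing in mycelia of 3 strains of Neurospora crassa, a filamentous fungus that degrades plant cell walls. The parent strain, Δ3βG, lacks 3 genes for β-glucosidases, the enzymes that split the disaccharide cellobiose into glucose. Δ3βGΔclp1 also lacks clp1 (NCU05853), which encodes a protein resembling cellodextrin transporters, and the strain is named Δ3βGΔncu05853 in the labels. Δ3βGΔcdt2Δclp1, named Δ3βGΔcdt2Δncu05853 in the labels, lacks in addition the cellodextrin transporter gene cdt-2 (NCU08114). Each strain was grown for 16 h in sucrose and then kept for 4 h in 2% cellobiose. Each strain had 1 library, with 8586155 reads assigned to genes in Δ3βG, 9465639 in Δ3βGΔclp1 and 9808610 in Δ3βGΔcdt2Δclp1. No difference below therefore has a replicate check, no p-value is given, and the 95% intervals cover counting error only.

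clp1 and cdt-2 had few or no reads in the libraries that should lack them, while the deleted β-glucosidase genes had low counts, most of them above the floor of 3 reads. clp1 had 4190 reads in Δ3βG, 2 in Δ3βGΔclp1 and 0 in Δ3βGΔcdt2Δclp1, where a count of 0 has an upper 95% Poisson limit of 3.69. cdt-2 had 1907 reads in Δ3βG, 2842 in Δ3βGΔclp1 and 9 in Δ3βGΔcdt2Δclp1, the last being 0.547% of the Δ3βG level (upper limit 1.04%). The β-glucosidase genes gh1-1 (NCU00130), gh3-4 (NCU04952) and gh3-3 (NCU08755) had between 0 and 47 reads in the 3 libraries. gh1-1 had 18 reads in Δ3βG (95% Poisson interval 10.7 to 28.4), 47 in Δ3βGΔclp1 (34.5 to 62.5) and 0 in Δ3βGΔcdt2Δclp1. gh3-3 had 15, 14 and 21 reads, and gh3-4 had 5, 14 and 13.

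The first comparison set Δ3βGΔclp1 against Δ3βG. The question named by the series is how the loss of clp1 bears on the response to cellobiose. All 3 libraries came from mycelia after 4 h in cellobiose, with none from before the transfer or from another medium. Levels on cellobiose were therefore compared, and the change in response to it could not be measured. All 12 genes of glycolysis and fermentation had log2 ratios above 0 in Δ3βGΔclp1, with 1 at least 2-fold higher, and 4 of 5 genes of gluconeogenesis and the glyoxylate cycle had ratios below 0, with 1 at least 2-fold lower. Cellulase genes were at a low level in both strains. Alcohol dehydrogenase adh-1 (NCU01754) was 2.69-fold higher (95% counting interval 2.47 to 2.92), and phosphoenolpyruvate carboxykinase acu-6 (NCU09873) was 2.77-fold lower (2.69 to 2.86). The cellobiohydrolase gene cbh-1 (NCU07340) had 490 reads in Δ3βG and 722 in Δ3βGΔclp1, a ratio of 1.35 (1.20 to 1.52). Of 6545 genes with a mean of at least 10 CPM (reads scaled to library size), 37 were at least 2-fold higher and 44 at least 2-fold lower in Δ3βGΔclp1, and 98.8% lay within 2-fold. At or under the floor of 3 reads in both libraries were 1 of the 37 (NCU04012) and 2 of the 44 (NCU04870 and NCU09416), which leaves 36 and 42. Above that floor, 3 genes were at least 4-fold higher and 0 at least 4-fold lower. The counting interval excluded a ratio of 1 for 31 of the 37 and 40 of the 44.

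Among single genes, NCU04276 stood highest in Δ3βGΔclp1, with 206 reads in Δ3βG and 3964 in Δ3βGΔclp1, 17.7-fold higher (15.4 to 20.4). NCU07405 was 4.47-fold higher (4.02 to 4.98), NCU05338 4.26-fold (3.70 to 4.92), NCU07352 3.71-fold (2.35 to 6.07) and NCU04502 3.05-fold (2.92 to 3.20). NCU01546, NCU03421, NCU07853, NCU08044 and NCU08943 were higher by log2 ratios of 1.52 to 1.71. The lytic polysaccharide monooxygenase gene gh61-2 (NCU07760) had 2 and 7 reads, and its interval included a ratio of 1. At the other end, NCU06883 was 3.17-fold lower (2.56 to 3.96) and NCU06505 3.13-fold lower (2.73 to 3.59). NCU07339, NCU05751, NCU01861, NCU09049, NCU03918 and NCU07345 had log2 ratios between -1.70 and -1.34. NCU01076 had 9 and 3 reads, with an interval that included a ratio of 1. NCU04012 (0 and 3 reads), NCU04870 (2 and 0 reads) and NCU09416 (1 and 0 reads) were at or under the floor of 3 reads in both libraries, so no ratio is given for them.

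All 12 genes of glycolysis and fermentation had log2 ratios above 0, with a median of 0.63 at the 100th percentile of 10000 random lists matched on expression. They included glyceraldehyde phosphate dehydrogenase gpd-1 (NCU01528), 1.58-fold higher (1.53 to 1.62), and glucose phosphate isomerase gpi-1 (NCU07281), 1.57-fold higher (1.47 to 1.67). Of the 12, 1 was at least 2-fold higher, adh-1. The 5 genes of gluconeogenesis and the glyoxylate cycle had a median of -0.39 (percentile 0.17), with 4 below 0 and acu-6 at least 2-fold lower. All 9 genes of protein folding in the endoplasmic reticulum and of secretion were below 0, none by 2-fold, with a median of -0.34 (percentile 0.03). The chaperone gene grp78 (NCU03982) was the lowest of them, at -0.62. Markers of conidia and aerial hyphae had a median of -0.36 (percentile 0), with 9 of 12 below 0, among them the conidiation regulator fl (NCU08726) at -0.70. The hydrophobin gene eas (NCU08457), which made up 18.7% of gene reads in Δ3βG and 20.0% in Δ3βGΔclp1, had a log2 ratio of 0.12.

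The enzymes of plant cell wall degradation differed little between these libraries. Cellulases had a median log2 ratio of 0.37 (percentile 99.7; 6 of 8 above 0), and together took 0.0133% of gene reads in Δ3βG and 0.0162% in Δ3βGΔclp1. Lytic polysaccharide monooxygenases and cellobiose dehydrogenase had a median of 0.23 (percentile 98.8), pectin-degrading enzymes 0.28 (97.1), and the remaining β-glucosidases 0.52 (98.8), with none at least 2-fold apart except gh61-2. Hemicellulases had a median of -0.10 (percentile 6.72), which is the value of gh10-3 (NCU04997), a gene with 2 reads in each library. Without the 2 members at or under 3 reads in both libraries, gh10-3 and NCU04870, the median was 0.01 (percentile 53.55), with 9 of 17 above 0. NCU09664 (3 and 8 reads) was at least 2-fold higher, on too few reads to exclude a ratio of 1. Pentose catabolism genes had a median of 0.33 (percentile 98.4), with xylose reductase xr (NCU08384) at 0.97. Sugar transporters had a median of 0.09 (percentile 91.5), with 16 above 0 and 11 below, and NCU05627 and NCU01633 at least 2-fold lower. The cellodextrin transporter gene cdt-1 was 1.56-fold higher (1.44 to 1.70), and cdt-2, which is not in that list, stood at 137% of its Δ3βG level. Transcription factors of cellulase and carbon control had a median of 0.07 (percentile 75.7) and none at least 2-fold apart. Starch and sucrose hydrolases stood at -0.05 (percentile 34.6), with invertase inv (NCU04265) 2.51-fold higher (1.58 to 4.09). Clock and light genes stood at 0.04 (percentile 57.6), and heat shock and catalase genes at -0.18 (percentile 6.39). Of the 15 lists, 8 had medians outside the central 95% of random lists, which describes these 2 libraries and not the strains. The match used the mean of all 3 libraries. Enzymes abundant only in Δ3βGΔcdt2Δclp1, such as gh5-1 with 40 and 27 reads here, were thus matched to genes that can have far more reads. Percentiles of the enzyme and pentose lists, and the 8, may therefore be too extreme.

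The second comparison set Δ3βGΔcdt2Δclp1 against Δ3βG. Most cellulase and hemicellulase genes and the cellodextrin transporter gene cdt-1 were far higher in Δ3βGΔcdt2Δclp1, and the hydrophobin gene eas and 4 of 5 genes of gluconeogenesis and the glyoxylate cycle were far lower. cbh-1 had 637941 reads against 490, 1508-fold higher (1379.9 to 1651). Its share of gene reads was 0.00571% in Δ3βG and 6.50% in Δ3βGΔcdt2Δclp1. The cellobiohydrolase gene gh6-2 (NCU09680) was 1511-fold higher (1332 to 1720.4), and cdt-1 (NCU00801) 92.6-fold higher (86.6 to 99.0). eas was 46.2-fold lower (45.7 to 46.8), at 0.305% of gene reads. Of the 6545 genes, 1267 were at least 2-fold higher and 1008 at least 2-fold lower, and 65.2% lay within 2-fold. At least 4-fold apart were 539 higher and 286 lower genes. Strains lacking these β-glucosidases are known to induce cellulases on cellobiose, but the cellulase list took 0.0133% of gene reads in this Δ3βG library, so the ratios stand over a low level. Lag and sugar in the medium were not measured here.

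The balance between higher and lower genes depended on the scaling. Scaled on library totals, 882 genes were higher and 1765 lower, and without the 50 genes with most counts 899 and 1713. Scaled on all reads in the file the numbers were 1002 and 1465, and on library totals without eas 697 and 2515. These settings moved the median of all genes by -0.40, -0.38, -0.27 and -0.70 on the log2 scale. The last one leaves out eas, 18.7% of gene reads in Δ3βG and 0.305% in Δ3βGΔcdt2Δclp1. It keeps the cellulases, 12.2% in Δ3βGΔcdt2Δclp1, and so lowered the ratios of that library the most. Reads outside genes made up 9.64% of all reads in Δ3βG, 8.41% in Δ3βGΔclp1 and 5.16% in Δ3βGΔcdt2Δclp1, and reads with several alignments 6.36%, 4.91% and 2.48%.

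Of the 12 genes with the highest ratios, 10 belonged to the fixed lists of cell wall degrading enzymes. The xylanase gene gh11-2 (NCU07225) had 7 reads in Δ3βG and 48428 in Δ3βGΔcdt2Δclp1, 8012-fold higher (3888 to 19928). The hemicellulase list also held NCU04870, 3247-fold higher (898.5 to 26819.9) over 2 reads, NCU08785, 2212-fold (1165 to 4839), and the xylanase gene gh10-1 (NCU05924), 1425-fold (932 to 2303). The monooxygenase gene gh61-4 (NCU01050) was 1994-fold higher (1532 to 2647), gh61-7 (NCU00836) 1374-fold (898 to 2219.6), the endoglucanase gene gh5-1 (NCU00762) 1203-fold (883 to 1684) and the β-glucosidase gene gh3-6 (NCU07487) 1089-fold (826 to 1468). NCU04169 was 1330.5-fold higher (701 to 2911). NCU04012 had 0 and 458 reads and was at least 177-fold higher.

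The genes with the lowest ratios included app (NCU04533), 371-fold lower (170.3 to 1012), and NCU09734, one of the 10 most abundant genes of Δ3βG, 142-fold lower (128 to 158). The xylanase-family gene gh10-4 (NCU07130) was the 1 member of the hemicellulase list at least 2-fold lower, with 520 reads in Δ3βG and 2 in Δ3βGΔcdt2Δclp1, 225-fold lower (61.8 to 1859). NCU05093 (221 and 0 reads) was at least 63.6-fold lower and NCU08711 (161 and 0 reads) at least 46.3-fold lower. NCU09859, NCU00850, NCU05932, NCU05596, NCU00852 and NCU09391 had 1 to 3 reads in Δ3βGΔcdt2Δclp1, with ratios of 121-fold to 307-fold lower and intervals that began at 27.4-fold to 73.3-fold and ended at 1007-fold to 12142-fold. NCU03861 was 93.5-fold lower (59.0 to 158).

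**Figure D1:**
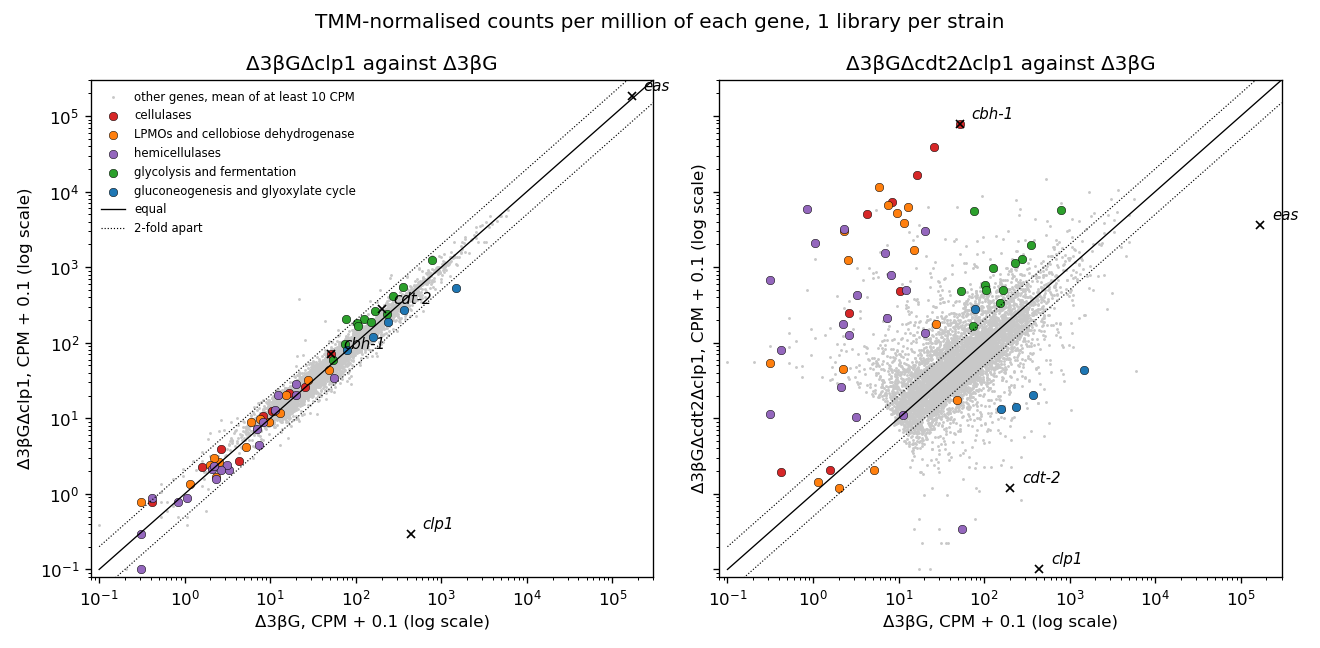
TMM-normalised CPM plus 0.1 of each gene in Δ3βGΔclp1 (left, y axis) and Δ3βGΔcdt2Δclp1 (right, y axis) against Δ3βG (x axes), all axes on a log scale, with 1 library per strain; grey points are genes with a mean of at least 10 CPM, coloured points are genes of 5 lists, the solid line marks equal values and the dotted lines a 2-fold difference. On the left 98.8% of genes lie within 2-fold, while on the right cellulases such as cbh-1 lie far above the line and eas far below it.

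By list, 7 of 8 cellulases were at least 2-fold higher, with a median log2 ratio of 9.87 (percentile 100), and the list took 12.2% of gene reads against 0.0133%. The remaining member, gh6-1 (NCU03996), had 14 and 16 reads. Lytic polysaccharide monooxygenases and cellobiose dehydrogenase had a median of 7.67 (percentile 100), with 11 of 15 at least 2-fold higher, among them cellobiose dehydrogenase cdh-1 (NCU00206), 493-fold (413 to 594). That median is the value of gh61-2, with 2 reads in Δ3βG and an interval of 70.3-fold to 2115-fold, and it was 6.73 with a prior of 5 counts and 8.66 over members of at least 10 CPM. NCU07974 and gh61-10 (NCU01867) of that list were 2.80-fold and 2.59-fold lower. Hemicellulases had a median of 6.33 (percentile 100), with 17 of 19 higher and gh10-4 lower. Pectin-degrading enzymes had a median of 4.38 (percentile 100; 5 of 6 higher), and the remaining β-glucosidases 2.17 (percentile 98.2; 3 of 3 higher). Pentose catabolism genes had a median of 1.92 (percentile 99.7; 4 of 5 higher), with xr 96.7-fold higher (70.6 to 136). On library totals without eas their median was 1.23, with 3 of 5 higher.

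Transcription factors of cellulase and carbon control had a median of 0.98 (percentile 95.6), with 5 of 11 at least 2-fold higher and 2 lower. On library totals without eas the median was 0.28, with 5 higher and 3 lower. clr-2 (NCU08042), a regulator of cellulase genes, was 221-fold higher (163 to 307), and clr-1 (NCU07705) 8.62-fold (7.94 to 9.37). NCU05846 was 49.3-fold higher (44.9 to 54.3), vib-1 (NCU03725) 20.4-fold (18.3 to 22.9) and the xylanase regulator xlr-1 (NCU06971) 19.4-fold (17.5 to 21.5). The carbon catabolite repressor cre-1 (NCU08807) was 2.09-fold lower (1.89 to 2.31) and rca-1 (NCU01312) 11.7-fold lower (9.71 to 14.2). Sugar transporters had a median of 1.05 (percentile 100), with 14 of 27 higher and 5 lower, NCU05897 being 29.1-fold higher (26.6 to 31.9) and NCU05627 8.32-fold lower (6.62 to 10.6). On library totals without eas their median was 0.35, with 11 higher and 9 lower.

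Medians of the lists of central carbon metabolism had the same signs as in Δ3βGΔclp1. All 12 genes of glycolysis and fermentation were at least 2-fold higher (9 on library totals without eas), with a median of 2.38 (percentile 99.97; 1.69 on those totals), among them adh-1, 71.2-fold (66.2 to 76.7), and gpd-1, 7.23-fold (7.05 to 7.41). Of the 5 genes of gluconeogenesis and the glyoxylate cycle, 4 were lower, with a median of -4.05 (percentile 0). acu-6 was 34.3-fold lower (30.9 to 38.3), isocitrate lyase acu-3 (NCU04230) 16.7-fold (13.8 to 20.3), malate synthase acu-9 (NCU10007) 18.4-fold (15.7 to 21.6) and the fructose bisphosphatase gene fbp-1 (NCU04797) 11.9-fold (9.80 to 14.6). Acetyl-CoA synthetase acu-5 (NCU06836) was 3.53-fold higher (3.24 to 3.84). Starch and sucrose hydrolases had a median of -2.52 (percentile 0.26), with glucoamylase gla-1 (NCU01517) 5.75-fold lower (5.44 to 6.07), gh13-2 (NCU09805) 22.9-fold lower (15.3 to 36.0) and inv 30.3-fold higher (20.5 to 46.8).

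Markers of conidia and aerial hyphae went both ways, with 3 of 12 at least 2-fold higher and 5 lower. Beside eas, con-13 (NCU07324) was 61.3-fold lower (40.4 to 98.2), fl 21.5-fold (19.2 to 24.1) and the carotenoid gene al-3 (NCU01427) 6.42-fold (6.12 to 6.74), whereas ccg-14 (NCU07787) was 9.28-fold higher (7.22 to 12.1). The list median was 0.47 (percentile 82.4). Of the settings tried, 1 turned it negative, library totals without eas, to -0.23 with 1 gene higher and 5 lower. Clock and light genes stood at 0.66 (percentile 76.3) and heat shock and catalase genes at 0.67 (percentile 84.7), and both also turned negative on that scale alone, to -0.03 and -0.02. The catalase gene cat-3 (NCU00355) had a log2 ratio of 3.80. Genes of folding in the endoplasmic reticulum and of secretion had a median of 0.70 (percentile 82.0), with 3 of 9 at least 2-fold higher, and 0.01 on that scale, with 0 of 9 higher. Of the 15 lists, 10 had medians outside the central 95% of random lists.

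**Figure D2:**
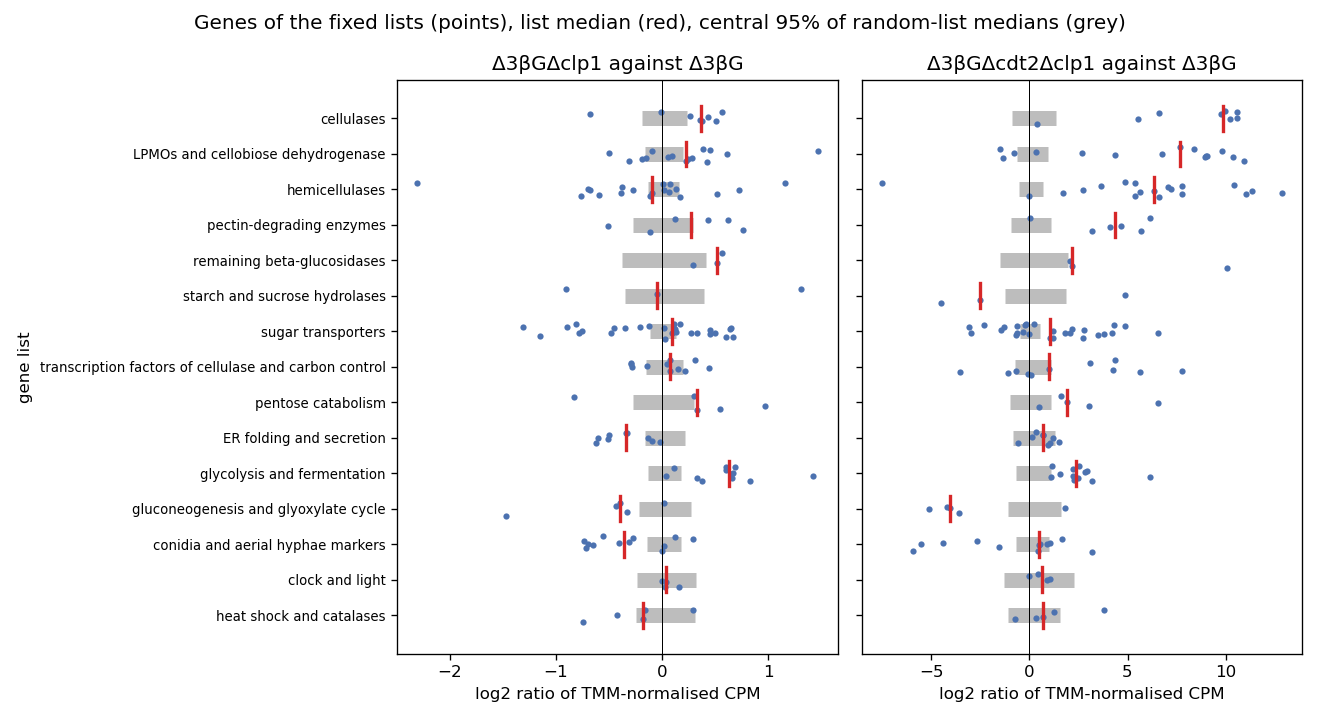
Log2 ratio of TMM-normalised CPM (x axis) of the genes of the 15 fixed lists (y axis) in Δ3βGΔclp1 (left) and Δ3βGΔcdt2Δclp1 (right), each against Δ3βG with 1 library per strain; points are genes, red bars list medians and grey bars the central 95% of medians of 10000 random lists matched on expression. The x axes differ in range: glycolysis has a median of 0.63 on the left and 2.38 on the right, and cellulases 0.37 and 9.87; medians of conidia, clock and heat shock genes on the right turn negative when library totals without eas set the scale.

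The third comparison set Δ3βGΔcdt2Δclp1 against Δ3βGΔclp1, strains that per the labels differ by cdt-2. gh1-1, a gene that both should lack, had 47 reads in Δ3βGΔclp1 and 0 in Δ3βGΔcdt2Δclp1. Further differences between these strains are therefore not excluded. No strain lacking cdt-2 but holding clp1 was measured. Loss of cdt-2 by itself thus cannot be told apart from its loss together with clp1. Most genes of the cellulase and hemicellulase lists were again far higher in Δ3βGΔcdt2Δclp1, and 4 of 5 genes of gluconeogenesis and the glyoxylate cycle lower. cbh-1 was 1115-fold higher (1036 to 1201) and gh11-2 8728-fold (4236 to 21710.1), and gluconeogenic acu-6 was 12.4-fold lower. Of the 6545 genes, 1082 were at least 2-fold higher (434 at least 4-fold) and 782 at least 2-fold lower (229 at least 4-fold). The 2-fold counts were 751 and 1541 on library totals, 742 and 1571 without the 50 genes with most counts, 817 and 1300 on all reads, and 556 and 2455 on library totals without eas.

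The 12 genes with the highest ratios in this comparison included gh10-1, gh5-1, gh61-7, gh6-2, gh61-4, NCU08785 and NCU04169, with log2 ratios of 10.33 to 11.48. NCU04870 (0 and 5608 reads) was at least 2358-fold higher, NCU09416 (0 and 448 reads) at least 188-fold, and NCU00449 1289-fold (503 to 4733). The lowest ratios were those of app, 465-fold lower (213 to 1267), NCU09734, 136-fold (122 to 151), and gh10-4, 141-fold (38.7 to 1166). NCU05093 was at least 41.0-fold lower and NCU08711 at least 38.3-fold. NCU00850, NCU05932, NCU09859, NCU05596, NCU00852, NCU01402 and NCU03861 had log2 ratios of -6.95 to -6.13. The first 5 of these had 1 to 3 reads in Δ3βGΔcdt2Δclp1, and the intervals of their ratios began at 23.6-fold to 47.0-fold lower.

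Cellulases had a median log2 ratio of 9.51 (7 of 8 at least 2-fold higher), monooxygenases and cellobiose dehydrogenase 6.35 (11 of 15 higher and 3 lower), hemicellulases 6.26 (17 of 19 higher), and pectin-degrading enzymes 4.33 (5 of 6 higher), each at percentile 100. The hemicellulase median is the same with NCU04870 at its bound, which lies above it. The remaining β-glucosidases stood at 1.88 (percentile 98.1), pentose catabolism at 1.62 (99.6), sugar transporters at 0.96 (100) and the transcription factors at 1.27 (99.3), with clr-2 177-fold higher. Glycolysis and fermentation had a median of 1.78 (percentile 99.94; 9 of 12 higher), gluconeogenesis and the glyoxylate cycle -3.63 (percentile 0; 4 of 5 lower), and starch and sucrose hydrolases -2.47 (percentile 0.2). Genes of folding in the endoplasmic reticulum and of secretion stood at 1.05 (percentile 96.0; 5 of 9 higher), conidia and aerial hyphae markers at 0.90 (97.8; 6 higher and 4 lower of 12), and heat shock and catalase genes at 0.84 (91.4). Clock and light genes stood at 0.64 (percentile 78.7) and turned to -0.06 on library totals without eas. On those totals 9 sugar transporters were at least 2-fold higher and 8 lower (median 0.25), against 13 and 3 as reported. The numbers higher were then 5 of 11 transcription factors with 3 lower (0.57), 2 of 5 genes of pentose catabolism (0.92), 6 of 12 of glycolysis and fermentation (1.07), 1 of 9 of folding and secretion (0.34) and 1 of 12 conidia markers with 5 lower (0.20). Of the remaining β-glucosidases, 2 of 3 were then higher (1.18). Of the 15 lists, 12 had medians outside the central 95% of random lists.

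The last comparison asked whether the genes that differed in Δ3βGΔclp1 also differed in Δ3βGΔcdt2Δclp1, both against Δ3βG. Of the 37 genes at least 2-fold higher in Δ3βGΔclp1, 34 were also at least 2-fold higher in Δ3βGΔcdt2Δclp1, among them NCU04276, NCU07405 and adh-1, where independent lists would share 7.16. Of the 44 lower genes, 30 were shared, among them acu-6 and NCU06505, where independent lists would share 6.78. Above the floor of 3 reads, 33 of 36 higher and 30 of 42 lower genes were shared. The filter on low counts used the mean CPM of all 3 libraries. gh61-2, with 2, 7 and 441 reads in Δ3βG, Δ3βGΔclp1 and Δ3βGΔcdt2Δclp1, passed it only through the last. For such genes a higher level in Δ3βGΔcdt2Δclp1 was set by the filter, so 7.16 may be too low a baseline. Their number was not counted. Of the 37, 6 had counting intervals that include a ratio of 1. Simulated unchanged libraries against the same control gave 2.09 shared higher genes of 3.77 and 0.89 shared lower genes of 3.28. Across the 6545 genes, which are not independent replicates, Pearson's r was 0.488 and Spearman's rho 0.577, against a simulated r of 0.533 and a simulated rho of 0.487. The covariance of the log2 ratios was 0.257 against a simulated 0.00935, a difference of 0.248. Pearson's r thus showed no excess over the simulation, unlike the shared genes, rho and the covariance. The simulated libraries hold no changed genes, so the 2 covariances are not on a like footing. The simulation holds counting error only and the single Δ3βG library cannot be split, so part of the excess in those measures may come from the shared control.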

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

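All tests in this part, and the bounds set for them, were chosen after the results were seen.

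In 7 genes the ratio to Δ3βG was at least 2-fold in opposite directions in Δ3βGΔclp1 and Δ3βGΔcdt2Δclp1, with counting intervals that exclude 1 in both; the difference was not tested, having 1 library per strain. The log2 ratio in Δ3βGΔclp1 minus that in Δ3βGΔcdt2Δclp1 was -6.67 for NCU07339, -5.76 for NCU05751, -3.15 for NCU08193, -2.61 for NCU05069 and -2.56 for NCU01861, which were lower in Δ3βGΔclp1 and higher in Δ3βGΔcdt2Δclp1. It was 2.77 for NCU09738 and 2.13 for NCU07309, which were higher in Δ3βGΔclp1 and lower in Δ3βGΔcdt2Δclp1. NCU07339 had 16, 5 and 447 reads in Δ3βG, Δ3βGΔclp1 and Δ3βGΔcdt2Δclp1, and NCU09738 had 1386, 3694 and 429. NCU05751 had 123, 45 and 1963 reads, and NCU08193 had 59, 30 and 215. The filter on low counts used the mean CPM of all libraries. NCU07339, NCU05751 and NCU08193 passed it only through Δ3βGΔcdt2Δclp1. The filter thus favoured a higher level of these genes there, so their opposite directions may be partly its result.

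Of the 81 genes at least 2-fold apart in Δ3βGΔclp1, 68 went the same way in Δ3βGΔcdt2Δclp1 and 64 went on the same way from Δ3βGΔclp1 to Δ3βGΔcdt2Δclp1; without genes at or under 3 reads in both Δ3βG and Δ3βGΔclp1 these numbers were 67 and 63 of 78. Some of the higher genes, such as gh61-2, passed the filter on low counts only through Δ3βGΔcdt2Δclp1. Their higher level there was set by the filter, and these numbers include them. Counting error in the shared Δ3βG library is argued against, because 100 simulated unchanged libraries gave at most 13 genes at least 2-fold apart. RNA of Δ3βGΔcdt2Δclp1 mixed into the Δ3βGΔclp1 library would need a median share of 6.20% (lower quartile 1.64%) over 35 of the higher genes, while the reads of cbh-1 allow at most 0.0965%; the lower genes were not part of this test. Growth state, including a Δ3βG culture that stood apart from both other strains, and the loss of clp1 cannot be told apart, because each strain has 1 library.

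Between Δ3βGΔcdt2Δclp1 and Δ3βG, 2275 genes differed by at least 2-fold. Abundant genes such as eas and cbh-1 act on the others through 1 common factor per library, so if they alone had made this number, some factor would leave about as few genes as the 78 left in Δ3βGΔclp1 against Δ3βG. Over all factors up to a log2 of 3 either way, and without the 50 genes with most counts, the fewest left was 2218. A library of either other strain under this label is argued against by cdt-2, whose upper limit was 1.04% of the Δ3βG level. The state of a single culture and the deletions cannot be told apart with 1 library per strain, and a biological effect of the deletions remains open and untested.

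Cellulase reads in Δ3βG and Δ3βGΔclp1 were few beside those in Δ3βGΔcdt2Δclp1, so reads misassigned from that library could have made them. The 7 reads of gh11-2 in each library limit such misassignment to 0.0405% of the reads in Δ3βGΔcdt2Δclp1. Of 7 cellulases with at least 1000 reads there, 6 had a lower limit (99.9%, one-sided) above the reads this rate allows in both libraries; gh5-1 had it in Δ3βG alone, its 27 reads in Δ3βGΔclp1 having a lower limit of 13.7 against 16.8 allowed. cbh-1 had 0.0768% of its Δ3βGΔcdt2Δclp1 reads in Δ3βG and gh7-2 2.47%, so 1 common rate does not account for both. No biological explanation was tested for these low levels, in a strain background known to induce cellulases on cellobiose.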

How the results depend on the processing

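No paired analysis was possible because each strain has 1 library, and for the same reason no library could be left out. Planned settings come first and the 2 settings chosen after seeing the data, all reads in the file and library totals without eas, after them. Counts are given as higher and lower genes, at least 2-fold apart; where a setting is missing for a comparison, its count stayed within 1.5 times. Without a filter on low counts the counts were 342 and 293 for Δ3βGΔclp1 against Δ3βG, 1986 and 1607 for Δ3βGΔcdt2Δclp1 against Δ3βG, and 1750 and 1315 for Δ3βGΔcdt2Δclp1 against Δ3βGΔclp1, because more genes enter. With a minimum of 50 CPM fewer genes enter, and they were 19 and 16, 716 and 579, and 626 and 446. A prior of 5 counts, which draws in the ratios of genes with few reads, gave 25 and 37 for Δ3βGΔclp1 against Δ3βG, where 37 and 44 were reported. Library totals gave 1765 lower genes in Δ3βGΔcdt2Δclp1 against Δ3βG and 1541 against Δ3βGΔclp1, with cellulase medians of 9.47 and 9.12. Library totals without the 50 genes with most counts gave 1713 and 1571, with medians of 9.50 and 9.11. All reads in the file gave 1300 lower genes against Δ3βGΔclp1, with medians of 9.61 and 9.22. Library totals without eas gave 697 higher and 2515 lower genes against Δ3βG and 556 and 2455 against Δ3βGΔclp1, with medians of 9.18 and 8.81. These scalings shift all genes by 1 factor per library. The correlation of the log2 ratios of the strains lacking clp1 was 0.503 with a prior of 5 counts and 0.388 without a filter; the cause was not tested.

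With DESeq2 size factors the counts of all 3 comparisons stayed within 1.5 times, and so did the number of lists outside the central 95% of random lists under each scaling, with a prior of 5 counts and with list members of at least 10 CPM. That number was not recomputed for the changed filters on low counts. Of 441 ratios of named genes, 260 were at least 2-fold; under the settings tried 41 of these came below 2-fold in at least 1 setting and 0 changed sign. Of 45 list medians, 21 were at least 1 in size, 4 of these came below 1 in some setting and 0 changed sign. Of the values of named genes and of lists other than cellulases over all settings, 980 lay outside the counting interval of the reported value and 1960 inside it. Depth limits the genes with few reads, such as gh61-2 in Δ3βGΔclp1 and Δ3βG, whose ratio could not be separated from 1.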

Other observations

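The gene groups and the test in this part were chosen after the results were seen. They are the 15 symbol stems shared by at least 10 measured genes, and the smaller groups crp, gst and chs, picked for their values. Of the 15 stems, 8 had medians outside the central 95% of random lists in Δ3βGΔcdt2Δclp1 against Δ3βG (crf, gh, mig, mus, nuo, pex, stk and tim) and 7 inside it (acw, arg, cys, hsp, rpn, tca and vma). In Δ3βGΔclp1 against Δ3βG, 5 were outside (crf, gh, nuo, tim and vma) and 10 inside.

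Genes for mitochondrial complex I (symbols nuo) had log2 ratios above 0 in Δ3βGΔcdt2Δclp1 against Δ3βG in 29 of 29 cases, with 12 at least 2-fold higher and a median of 0.93 (percentile 99.93 of random lists). That median was 0.23 on library totals without eas. In Δ3βGΔclp1 28 of 29 were above 0 and 0 at least 2-fold higher, with a median of 0.22 (percentile 99.99). All 7 cytosolic ribosomal protein genes with the symbol crp were at least 2-fold higher in Δ3βGΔcdt2Δclp1, with a median of 2.02 (percentile 99.8), and 3 of 4 glutathione transferase genes (gst), with a median of 2.44. DNA repair genes with the symbol mus were below 0 in 21 of 21 cases, 6 of them at least 2-fold lower, with a median of -0.70 (percentile 0.435). Mitochondrial import genes (tim) had a median of -0.82 in Δ3βGΔcdt2Δclp1 (percentile 0.855), with 2 of 11 at least 2-fold lower, and -0.26 in Δ3βGΔclp1 (percentile 0.46), where 11 of 11 were below 0 and 0 at least 2-fold lower. The 5 chs genes had a median of -0.98 (percentile 4.72), inside the range of random lists, with 2 at least 2-fold lower and 1 higher. The medians of nuo, crp, gst, mus, tim and chs kept their sign under each scaling tried. In Δ3βGΔcdt2Δclp1 against Δ3βG their size did change with the setting. The medians smallest in size over the other settings were 1.33 for crp, 1.75 for gst, -0.68 for mus, -0.79 for tim and -0.98 for chs. Those largest in size were -1.39 for mus, -1.51 for tim and -1.68 for chs.

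In the gene order of assembly NC12, the genes next to cdt-2 and clp1 were higher in Δ3βGΔcdt2Δclp1, which was not tested against other genes. Next to cdt-2, NCU08113 had a log2 ratio of 5.72 against Δ3βG and msh3 (NCU08115) of 3.65. Next to clp1, NCU05852 had 3.10 and NCU05854 3.83 in Δ3βGΔcdt2Δclp1, but 0.11 and -0.27 in Δ3βGΔclp1, which lacks clp1 too. Of the 8 genes within 2 places of cdt-2 or clp1, 8 were at least 2-fold higher in Δ3βGΔcdt2Δclp1 than in Δ3βG, and so were 8 of the 12 within 2 places of the deleted β-glucosidase genes, with medians of 3.74 and 1.49. Of all 6545 genes compared, 19.4% were at least 2-fold higher. Those genes had a mean of at least 10 CPM, a filter not set for the neighbours, so the sets are unlike. Among the 8 of 12, NCU08753 had 4, 8 and 11 reads and NCU08757 6, 3 and 33 in Δ3βG, Δ3βGΔclp1 and Δ3βGΔcdt2Δclp1. On library totals without eas, 6 of the 8, 4 of the 12 and 10.6% of all genes were at least 2-fold higher. Among the 12, the log2 ratio ranged from -0.51 (NCU00133) to 4.80 (NCU08756), and the difference between the groups of neighbours was not tested.

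Along the genome, 6 runs of at least 4 neighbouring genes were all at least 4-fold apart in Δ3βGΔcdt2Δclp1 against Δ3βG on the TMM scale, 3 higher and 3 lower, and their number was not set against chance. Library totals without eas moved the median of all genes by -0.70. The higher runs whose lowest log2 ratios are 2.05 and 2.47 would hold genes under 4-fold on that scale. The higher runs had log2 ratios of 2.47 to 4.75 (NCU05165 to NCU05160), 2.75 to 7.01 (NCU08746 to NCU08750) and 2.05 to 8.41 (NCU10110 to NCU10106). In Δ3βGΔclp1 the first of these had 0.24 to 1.46, the second -1.07 to 1.35 and the third -0.10 to 1.46. That -0.10 equals the value of gh10-3, with 2 reads in each library, so it gives no direction. The lower runs had -6.85 to -2.84 (NCU04861 to NCU04867), -4.10 to -2.40 (NCU06812 to NCU06808) and -5.50 to -2.02 (NCU05819 to NCU05822). In Δ3βGΔclp1 these had -0.26 to 0.21, -0.36 to -0.10 and -0.52 to 0.12.

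As a hypothesis, the culture of Δ3βGΔcdt2Δclp1 may have been less limited for carbon than that of Δ3βG, which would go with lower gluconeogenesis, glyoxylate cycle and eas and higher glycolysis. Other values go against it: cbh-1 was 1508-fold and clr-2 221-fold higher, although carbon repression holds cellulase genes low, the repressor gene cre-1 was 2.09-fold lower, and acu-5 was 3.53-fold higher. The glyoxylate cycle runs partly in peroxisomes, so genes of peroxisome biogenesis (pex) would then be low as a group. Their median was -0.87, with 19 of 20 below 0 and 8 at least 2-fold lower, at percentile 0.06 of matched random lists, and it stayed negative under each scaling tried. In Δ3βGΔclp1 the pex median was -0.01 (percentile 48.5) although acu-6 was lower there too. The stem was picked from those listed after its value had been seen, values go both ways, and sugar in the medium was not measured here, so the hypothesis stays open.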
